A study of Mus musculus with 4 samples.

How the data were processed

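Single-nucleus RNA was measured in 4 libraries from the frontal cortex of wild-type C57BL/6J mice at postnatal day 56. Per the labels' protocols, nuclei were isolated by homogenization and filtering without a sucrose gradient, libraries were made with the 10x Genomics Chromium 3′ v3 chemistry, and sequencing used the Illumina NovaSeq 6000. Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3 were used, with no role given. The genome build, the gene annotation and the filter that kept these nuclei are not given in the sources used here. How doublets were treated is likewise not given in the sources used here, and no doublet caller was run, so a barcode is counted as 1 nucleus throughout. Of the deposited data, 2 lists of names were used here, the nuclei (library and barcode) and the genes (symbols). Neither list holds a measured value, so reads or molecules per nucleus are unknown, and every number below is a count of names. The lists are already filtered on nuclei by the authors, so a low number of nuclei can reflect tissue, loading or filtering alike.

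Libraries were assigned to sex, batch and replicate from the labels, and each barcode to its library from the library name in front of it. No library name was left without a sample. Replicate numbers follow the order of the records and pair nothing. The tests, the gene lists and the alternatives were fixed before the data were examined, except for those named as chosen later. Nuclei per library and the GC share of barcodes are given as mean and SD over 4 libraries, and male and female libraries were compared by an exact permutation test of the difference in means (two-sided).

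Barcodes shared by each pair of libraries were compared with the number expected from random draws from a list of about 6800000 sequences, the approximate size of the kit's list, by an exact hypergeometric test. The test was made two-sided by doubling the smaller tail, with Benjamini-Hochberg adjustment over 6 pairs at a threshold of 0.05. The kit's list itself was not used here, and its size, its base pairing at positions 8 and 9 and the oligo sequences are background knowledge of the chemistry, not taken from these data. Ratios of observed to expected numbers carry exact Poisson 95% intervals, which cover counting error only. Shared barcodes within and across sequencing batches, and barcode pairs that differ at 1 base within and between libraries, were compared by exact conditional binomial tests (two-sided). Added after the values were seen, barcodes were called unusual when they matched a stretch of 16 bases of the template switch oligo or of the Read 1 primer site, on either strand with at most 1 mismatch, or when bases 8 and 9 were none of the 4 usual pairs TC, CA, AG and GT.

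Gene names were matched to the symbols of GENCODE M21 on GRCm38 by exact spelling, and coordinates are those of GENCODE M21. The authors' own build may differ, so chromosomes and biotypes describe the matched symbols in GENCODE M21 and not the authors' annotation. Synonyms came from the RefSeq gene table of GRCm38.p6, and names and, for a single test, biotypes were taken from it. Each chromosome and biotype was compared with the rest of the annotated symbols by Fisher's exact test (two-sided, Benjamini-Hochberg). The rule for named genes was set on the fixed lists of cell type markers, nuclear, cytoplasmic, sex-linked, circadian and immediate early genes. Absent members are all named, up to 30 per list, and of those present the first 4 of each list in the order written. Some genes that this rule takes are not reported here. Genes and families named outside this rule were chosen after their values were seen.

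The overlap test was tested on simulated data with 40 planted shared barcodes. In 200 runs the planted pair was recovered in 100% and any false pair was called in 1.5%. The smallest real overlap, for replicates 1 and 4, was 13 shared barcodes against 5.38 expected. Recovery of overlaps smaller than the planted 40 was not examined, nor were false calls under another pool size. The chromosome test was run 50 times on 55418 simulated genes with 1 chromosome at 50% against 40% elsewhere. It recovered the planted chromosome in 100% of runs and called 2.45% of the other chromosomes, and with none planted it called 0%. The planted chromosome was chromosome 7, the class with the most symbols (4709), so recovery of smaller classes was not examined. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

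The alternatives were other pool sizes, leaving out shared or unusual barcodes, batch A2 alone, the first 8 positions of the barcode, pairs differing at 1 or 2 bases, synonyms, a protein-coding background, and leaving out each replicate in turn. The 3 planned results that need expression values, sex differences per gene, depth and genes per nucleus, and cell type composition, were not run, because expression values were not analysed here.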

Results

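Nuclei from the rostral frontal cortex of wild-type C57BL/6J mice, an inbred laboratory strain, were profiled at postnatal day 56 by droplet single-nucleus RNA sequencing, in a series whose title names ambient RNA (free RNA captured together with a nucleus) as its subject. The 4 libraries formed a single wild-type group. Replicates 1 and 2 (libraries YL01 and YL08) were labelled male and replicates 3 and 4 (libraries YL10 and YL12) female. Replicate 1 was prepared and sequenced in batch A1 and the other 3 in batch A2, and each library had its own RNA preparation batch. The labels did not state that each library came from a separate animal, so the permutation tests of male against female libraries measure only the spread between these samples. The p-values for shared and near-identical barcodes take barcodes as the units and measure counting error only. The values examined were the names of 29034 nuclei and of 21967 genes. Expression values per nucleus were not analysed here, and the depth per nucleus is therefore unknown.

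The presence of the fixed marker lists in the gene list was examined first. Of all protein-coding genes without provisional names (Gm, Rik and versioned symbols) 96.8% were named, so nearly complete lists carry no information on which cell types were sampled. All 12 markers of excitatory neurons were named in it, among them Slc17a7, the vesicular glutamate transporter, the kinase gene Camk2a and Nrgn, which encodes neurogranin. All 10 markers of inhibitory neurons were named too, including the glutamate decarboxylase genes Gad1 and Gad2, the vesicular GABA transporter gene Slc32a1 and Pvalb, which encodes parvalbumin. The 7 astrocyte markers were complete, with the water channel gene Aqp4, the glutamate transporter genes Slc1a2 and Slc1a3 and the connexin gene Gja1 among them. The 7 oligodendrocyte markers were complete as well, including the myelin genes Mbp, Mog and Mobp, as were the 6 markers of oligodendrocyte precursors, with Pdgfra, Cspg4, Vcan and Olig1 among them. Of the 7 microglial markers 6 were named, among them the receptor genes Cx3cr1, P2ry12 and Csf1r and the complement gene C1qa.

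Markers of the vessels and of cells from outside the cortical tissue were complete. They comprised 5 endothelial genes (Flt1, Cldn5, Pecam1 and Cdh5 among them), 5 mural genes (Pdgfrb, Rgs5, Kcnj8 and Acta2 among them) and the 4 genes of vascular leptomeningeal cells, Dcn, Col1a1, Col1a2 and Lum. The 3 ependymal and choroid plexus genes Foxj1, Ttr and Tmem212, the 3 haemoglobin genes of red blood cells, Hbb-bs, Hba-a1 and Hba-a2, and the 3 T cell genes Cd3e, Cd3d and Cd8a were also named.

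The fixed lists of nuclear and of cytoplasmic RNAs were represented to different extents. Of 6 RNAs retained in the nucleus, 1 was named, Snhg11, which GENCODE M21 annotates as protein-coding. The other 5 were absent under their symbol and any synonym. These were the long noncoding RNAs Malat1 (chromosome 19, 5795690 to 5802672), Neat1 (chromosome 19, 5824708 to 5845478), Meg3 (chromosome 12, 109541001 to 109571726), Xist (chromosome X, 103460366 to 103483254) and Miat (chromosome 5, 112213228 to 112229395), all annotated as lincRNA in GENCODE M21 on GRCm38. All 8 cytoplasmic RNAs that can be carried as ambient RNA were named, among them Camk2a, Nrgn and the synaptic vesicle fusion gene Snap25. These 8 were all annotated as protein-coding. Of all annotated protein-coding genes 88.9% were named, against 10 of 5843 lincRNA genes. The lists therefore differ in biotype as well as in location, and the contrast cannot be read as a difference between nuclear and cytoplasmic RNA.

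Mitochondrial genes, whose transcripts are made outside the nucleus, were represented by 13 names, which were all 13 protein-coding genes of that genome. The other annotated mitochondrial genes, the ribosomal RNA genes mt-Rnr1 and mt-Rnr2 and the transfer RNA genes, were absent, so that 13 of 37 annotated symbols were named. The absent transfer RNA genes were mt-Ta, mt-Tc, mt-Td, mt-Te, mt-Tf, mt-Tg, mt-Th, mt-Ti, mt-Tk, mt-Tl1, mt-Tl2, mt-Tm, mt-Tn, mt-Tp, mt-Tq, mt-Tr, mt-Ts1, mt-Ts2, mt-Tt, mt-Tv, mt-Tw and mt-Ty. Of 98 protein-coding genes whose symbols begin with Rpl or Rps and a digit, 96 were named (98.0%, exact 95% interval 92.8 to 99.8). This class was set by the symbol alone, so it is not an exact count of ribosomal protein genes. The 2 absent ones were Rpl10-ps3 and Rpl36a-ps1.

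Sex can be read from X-inactivation RNAs and from genes of the Y chromosome. The X-inactivation RNA Xist was absent, as was its antisense partner Tsix (chromosome X, 103431517 to 103484957, plus strand, annotated as antisense). The 4 listed Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y were named, so 4 of 6 sex-linked genes were present. All 14 circadian clock genes were named, including the transcription factor genes Clock, Arntl and Npas2 and the repressor gene Per1. All 12 immediate early genes, which respond to neuronal activity, were named too, Fos, Fosb, Fosl2 and Jun among them. Over all lists, 110 of 118 entries were present by exact symbol and 111 with synonyms and any letter case.

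The gene list was next compared with all annotated genes, by name. Of the 21967 names, 19609 (89.3%) matched 1 of the 55418 gene symbols of GENCODE M21, and 2052 of the 2358 unmatched names (87.0%) ended in a version number. Protein-coding genes made up 99.7% of the matched names. Of 21991 annotated protein-coding genes 19549 were named (88.9%), against 60 of 33427 genes of other biotypes (0.179%). Among the latter were 10 of 5843 lincRNA genes and 5 of 2958 antisense genes. Of 45 biotypes, 1 (protein-coding) was named more often than the rest and 32 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted).

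Gene families with little known use in the cortex were named nearly in full. Of 1134 protein-coding olfactory receptor genes (Olfr), 1131 were named, and of 332 vomeronasal receptor genes (Vmn), 325. Predicted gene models and clone-based names were the exception. Of 1507 protein-coding gene models (Gm), 296 were named (19.6%, exact 95% interval 17.7 to 21.7), and of 587 protein-coding Rik clones, 72 (12.3%, 9.72 to 15.2). These classes provided 1726 of the 2442 absent protein-coding symbols. The list also held 2064 names that end in a version number, 2052 of them without a match. Some Gm and Rik genes may therefore stand in it under another name. Matching by synonyms and without version numbers raised the protein-coding genes named from 19549 to 19824. Names that this wider match does not cover were not tested.

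The named share differed between chromosomes. With all annotated genes as the background, 9 of 23 chromosome classes (the unplaced scaffolds counted as a class) were named more often than the rest and 9 less often. Chromosome 11 was the highest, with 1503 of 3003 genes named (50.05%, adjusted p = 4.59e-63, Fisher's exact test), and chromosome Y the lowest of the assembled chromosomes, with 55 of 1570 (3.50%, adjusted p = 1.73e-213, Fisher's exact test). Protein-coding genes made up 99.7% of the matched names, so these shares mostly follow how many annotated genes of a chromosome are protein-coding. That number was 1637 of 3003 on chromosome 11 and 183 of 1570 on chromosome Y. Among protein-coding genes alone, 10 classes were higher and 4 lower. The lower classes were chromosome 14 (672 of 901, 74.6%), chromosome X (759 of 948, 80.1%), chromosome Y (55 of 183, 30.1%) and the scaffolds (0 of 68). When Gm, Rik and versioned names were also left out of the background, a comparison added after the values were seen, no class was higher and 2 were lower, chromosome X (732 of 792, 92.4%, adjusted p = 9.74e-09, Fisher's exact test) and the scaffolds (0 of 8). Chromosome 14 then stood at 97.8% (662 of 677) and chromosome Y at 88.2% (15 of 17). A gene counted as absent may stand in the list under an older name, and neighbouring genes of 1 family are not independent, so these p-values describe the list and not single genes.

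**Figure D1:**
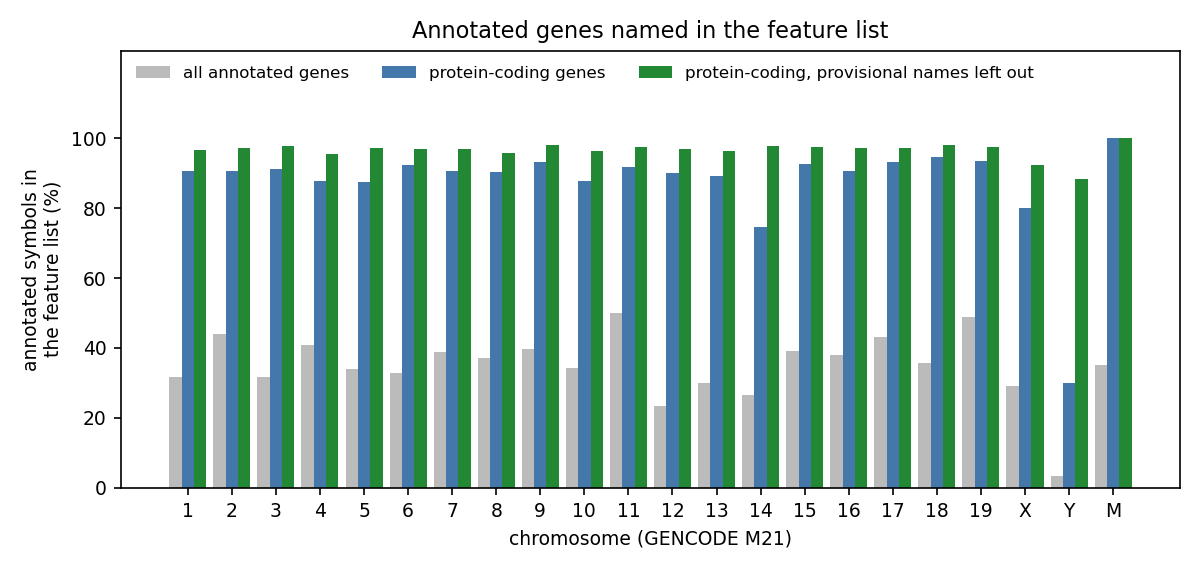
Share of annotated gene symbols named in the gene list (y axis, percent) for each chromosome of GENCODE M21 (x axis), with all annotated genes, protein-coding genes, or protein-coding genes without provisional names (Gm, Rik and versioned names) as the background. Chromosome Y stands at 3.50% of all its annotated genes, 30.1% of its protein-coding genes and 88.2% of those without provisional names.

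The libraries held 6217 (replicate 1), 8331 (replicate 2), 8603 (replicate 3) and 5883 nuclei (replicate 4). The mean was 7258.5 ± 1406 nuclei (SD, n = 4), a coefficient of variation of 19.4%. Male libraries averaged 7274 ± 1495 nuclei (SD, n = 2) and female libraries 7243 ± 1923 (SD, n = 2). The difference of 31 nuclei was smaller than the spread within either sex (exact permutation test, two-sided, p = 1), and 2 libraries against 2 cannot give a p below 0.333. Its sign turned without replicate 2 (-1026) or replicate 4 (-1329), and it was 1088 without replicate 1 and 1391 without replicate 3. Within batch A2, which held 1 male and 2 female libraries, the difference was likewise 1088 nuclei, and batch A1 held a male library only.

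**Figure D2:**
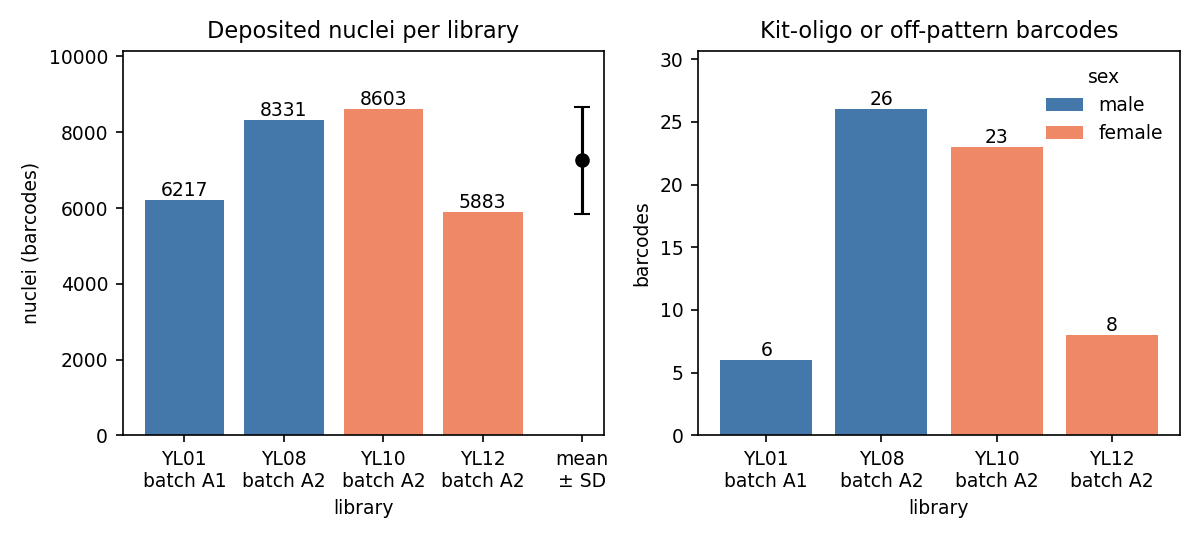
Left, number of nuclei (y axis) in each of the 4 libraries (x axis), coloured by sex, with the mean and SD over the 4 libraries as a black point and bar. Right, number of barcodes per library that match a kit oligo or lie outside the usual pattern at positions 8 and 9, which range from 6 in YL01 to 26 in YL08.

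Each nucleus carries a barcode of 16 bases, and independent libraries should share barcodes by chance alone. The 29034 names comprised 28911 distinct barcodes, of which 28802 occurred in 1 library, 100 in 2, 4 in 3 and 5 in all 4. Each of the 6 pairs of libraries shared more barcodes than random draws from about 6800000 kit sequences would give. The overlap was largest for replicates 2 and 3, with 43 shared against 10.5 expected (4.08-fold, adjusted p = 5.86e-13, exact hypergeometric test, two-sided). It was smallest for replicates 1 and 4, with 13 against 5.38 (2.42-fold, adjusted p = 0.00736, exact hypergeometric test, two-sided). This order rests on unusual barcodes, those that match a kit oligo or lie outside the usual base pattern at positions 8 and 9. Without them the ratio was 2.00 for replicates 2 and 3 and 1.49 for replicates 1 and 4, while the highest was 2.24 (replicates 1 and 2) and the lowest 1.39 (replicates 2 and 4). Over all pairs, 142 shared barcodes stood against 46.1 expected, a ratio of 3.08 (95% exact Poisson interval 2.60 to 3.63). This excess depended on the assumed number of kit sequences and on a small set of barcodes. Each of 2 changes chosen after the values were seen left an excess. The ratio was 1.54 with a pool of 3400000 sequences (1.30 to 1.82, with 1 of 6 pairs above expectation) and 1.90 with the unusual barcodes left out (1.52 to 2.34, 4 of 6 pairs). With both changes together, 87 stood against 91.7 (ratio 0.949, 0.760 to 1.17).

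The 3 pairs within sequencing batch A2 shared 84 barcodes against 25.2 expected, and the 3 pairs that join the batches shared 58 against 20.9. The ratio of the 2 rates was 1.20 (95% interval 0.848 to 1.71), which did not differ from 1 in an exact conditional binomial test (two-sided, p = 0.312). It was 0.902 without replicate 3 and 0.930 without the unusual barcodes.

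**Figure D3:**
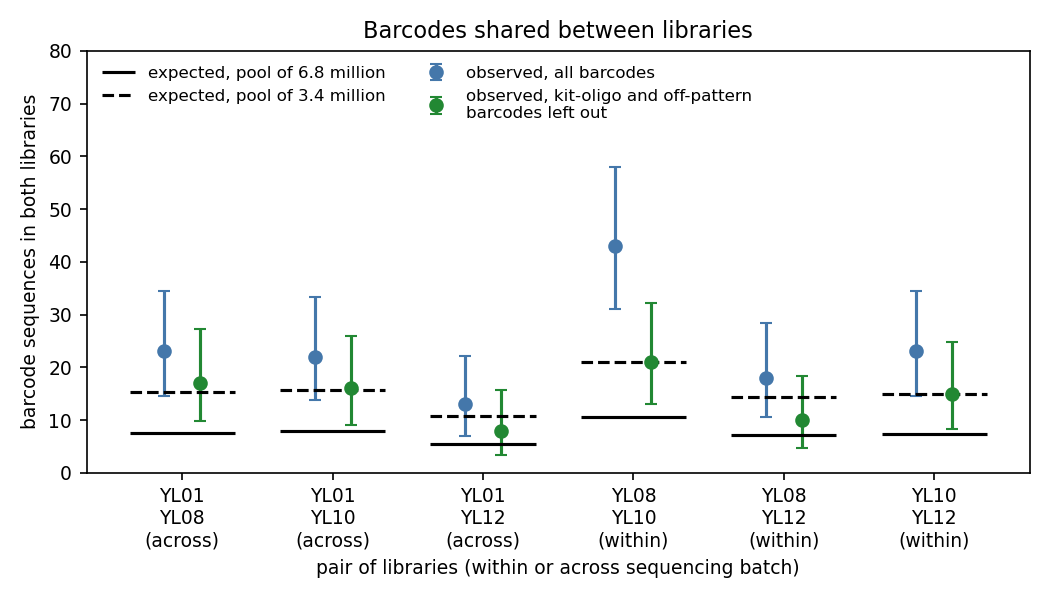
Number of barcode sequences present in both libraries (y axis) for each pair of libraries (x axis), for all barcodes and with kit-oligo and off-pattern barcodes left out. Bars are 95% exact Poisson intervals, and lines mark the numbers expected from pools of 6800000 and 3400000 sequences; with all barcodes the counts range from 13 to 43.

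Barcodes that differ at 1 base, as sequencing errors would make them, were rare within and between libraries alike. Without unusual barcodes there were 0 such pairs within and 0 between libraries, so their rarity is no measure of sequencing errors. With all barcodes there were 2 such pairs within libraries and 4 between libraries, a rate ratio of 1.45. All of them came from 1 pair of sequences, ATACACGACGCTCTTC (in replicates 2 and 3) and CTACACGACGCTCTTC (in replicates 2, 3 and 4), both of which match the Read 1 primer site, so they are not independent and the planned test says nothing about other barcodes. For pairs that differ at 1 or 2 bases there were 962 within and 2781 between libraries, a rate ratio of 0.999992 (95% interval 0.928 to 1.08, exact conditional binomial test, two-sided, p = 1). The GC share of the barcodes was 49.7% ± 0.129 (SD, n = 4). It was 49.7% in male and 49.8% in female libraries, a difference of -0.126 percentage points that was no larger than the spread between libraries (exact permutation test, two-sided, p = 0.667) and that turned to 0.00404 without replicate 2.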

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

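The tests of explanations in this part were all chosen after the results were seen; the planned values are the GC shares and the counts of shared barcodes.

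The GC share of the barcodes was 49.5% in replicate 2 (YL08), apart from 49.8% in each of the other 3 libraries. The difference of replicate 2 from their mean was -0.257 percentage points. By Dixon's criterion, its gap to the nearest library was 0.936 of the whole range. Chance sets apart about 1 in 20 groups of 4 values in this way, and 5 measures were checked. By counting error alone the SD of a GC share was 0.137 percentage points in replicate 2 and 0.135 to 0.163 in the others. The SD over the 4 libraries (0.129) was no larger, so the gap may be counting error.

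The first pattern is that libraries share more barcodes than random draws from about 6800000 sequences give. Index hopping between libraries sequenced together, as the whole cause, is argued against by the pairs that join the 2 sequencing batches, which without unusual barcodes still shared 1.97 times the number expected from 6800000 (95% interval 1.42 to 2.68). A candidate explanation, which assumes from background knowledge that kit sequences form pairs complementary at bases 8 and 9, is that each library draws mostly from a single member of each pair: of 100 identical or complementary pairs between libraries 13% were complementary (7.11 to 21.2), where equal use of both members would give 50% under that assumption (exact binomial test, two-sided, p = 1.31e-14). The identical pairs are the excess to be explained (87 against 45.9 expected from 6800000). Any source of extra identical barcodes lowers the complementary share, so this p-value partly restates the excess. Under the same assumption, random draws from all 6800000 sequences would also give 45.9 complementary pairs, against the 13 seen. A strict limit to a single member would give no complementary pair unless the usable part holds both, so the 13 pairs seen stay open. No biological explanation was tested, since the design names none for barcode sequences.

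The second pattern is the 9 barcodes present in 3 or 4 libraries. Chance repeats of real bead barcodes are argued against by the 0.129 such barcodes expected from 3400000 sequences (exact Poisson test, one-sided, p = 2.36e-14). The sequence of a kit oligo read in place of a barcode may account for them, since 9 of 9 match the template switch oligo or the Read 1 primer site, against 3 of 28802 barcodes found in 1 library (Fisher's exact test, two-sided, p = 5.84e-33). Those in all 4 libraries, such as AAGCAGTGGTATCAAC and GTGGTATCAACGCAGA, match the former, and those in 3, such as CACGACGCTCTTCCGA, the latter. Whether the nuclei named by these barcodes hold RNA of real nuclei was not tested, as expression values were not analysed here.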

How the results depend on the processing

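The settings that leave out unusual barcodes, the pool of 3400000 and the background without Gm, Rik and versioned names were chosen after the values were seen. The mean number of nuclei stayed within 1 SD under every alternative run, and the male minus female difference ranged from -1329 to 1391 when each replicate was left out, turning sign without replicate 2 (-1026) or 4 (-1329). Leaving out any replicate leaves 1 library of a sex, and no test was run there. For the barcodes' GC share, the first 8 positions alone gave 49.2%, and the sex difference ranged from -0.255 to 0.00404, the latter without replicate 2. The ratio of observed to expected shared barcodes kept its direction with a pool of 6000000 and without each replicate (2.67 to 3.38); it was 1.11 with a pool estimated across batches (which sets the pairs across batches to 1 by construction) and 0.949 with unusual barcodes left out and a pool of 3400000. Pairs above expectation numbered 0 with the estimated pool, 1 with 3400000, 0 with both changes, and 3 to 3 of 3 without a replicate, where fewer pairs exist by construction. Shared barcodes within against across batches gave 0.930 without unusual barcodes and 0.902 to 1.40 without each replicate, lowest without replicate 3; without replicate 1 no pair joins the batches and no value exists. Near-identical barcodes gave 0.999992 for pairs that differ at 1 or 2 bases, 0.999707 when unusual barcodes were also left out, and 0.962 to 1.94 without each replicate, lowest without replicate 1; the values at 1 base rest on 1 pair of oligo sequences, and no pair was left without unusual barcodes. Chromosomes named less often numbered 4 with the protein-coding background and 2 without provisional names, where those named more often numbered 0. For each of these changes the cause was not tested, beyond the smaller number of libraries or names. Symbol and marker counts stayed within 1.5 times. The sex differences per gene, depth and genes per nucleus, and cell type composition were not run, since expression values were not analysed here. No paired analysis was possible because the replicate numbers pair nothing. Depth per nucleus is unknown, so whether it set which nuclei were kept was not tested, and 2 libraries per sex limit every sex comparison.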

Other observations

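All comparisons in this part were chosen after the values were seen, except the counts of genes by chromosome and biotype, which were planned, and the RefSeq biotype test, which was set after the pattern but before its own result was seen.

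Among protein-coding genes of chromosome X with settled names, 60 of 792 were absent by exact symbol, and 16 of these were found under a synonym. The 3 families below were picked after the absent names were read, and their clustering was not tested. The testis histone variant family H2al1 had 0 of 14 genes named, with or without synonyms. Of 30 genes of the family Btbd35f 14 were named, and 16 with synonyms. The retrotransposon-derived genes Rtl had 0 of 7 named by symbol and 7 of 7 with synonyms.

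On chromosome 14, 229 of 901 protein-coding genes were absent, of which 214 had Gm, Rik or versioned symbols. On chromosome Y these numbers were 128 of 183 and 126, and on chromosome X 189 of 948 and 129.

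The third pattern is that almost none of the names that match an annotated symbol is a gene that is not protein-coding, Malat1, Neat1, Meg3, Miat, Xist and Tsix being absent. Removal of genes not detected in these nuclei is argued against as the cause, since 99.3% of protein-coding olfactory and vomeronasal receptor genes were named (1456 of 1466, against 18093 of 20525 other protein-coding genes). That only genes annotated as protein-coding were counted stays open, since the 60 named genes of other biotypes could not decide it. Of the 45 with a RefSeq biotype, 4 were protein-coding there (8.89%, exact 95% interval 2.48 to 21.2). This stood against 458 of 17085 genes not named (2.68%, Fisher's exact test, two-sided, p = 0.0326). Only 75% of the 60 had such a biotype, under the 80% set for the test, so the test is void and no direction is read from it. The 2358 names without a match (10.7% of the list) have no biotype here. If every such name were a gene of another biotype, 7.23% of those genes would be named, against 88.9% of protein-coding genes. No biological explanation was tested.

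Of the 28911 distinct barcodes, 99.9% carried 1 of 4 base pairs at positions 8 and 9, TC (7417), CA (7358), AG (7111) or GT (7003). The other 22 barcodes recurred in 86.4% of cases in 2 or more libraries, against 0.312% of barcodes with the usual pairs. Of these 22, 12 were found in replicates 2 and 3 and no other library, and 9 of the 12 matched neither oligo, among them the simple repeats TCCTTCCTTCCTTCCT and TTCTTTCTTTCTTTCT. Unusual barcodes made up 0.0965% of nuclei in replicate 1 (exact 95% interval 0.0354 to 0.210), 0.312% in replicate 2 (0.204 to 0.457), 0.267% in replicate 3 (0.170 to 0.401) and 0.136% in replicate 4 (0.0587 to 0.268).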
